A study of Mus musculus with 8 samples.

How the data were processed

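Gene expression was measured on 8 Affymetrix Mouse Genome 430 2.0 arrays, one per sample of cells sorted from mouse skin. Per the labels, total RNA was extracted with a QIAGEN RNeasy micro kit, 5 ng was amplified with the NuGEN Ovation Pico WTA system, and the cDNA was fragmented and biotin-labelled with the NuGEN Encore module. Amplification from so little RNA can raise the scatter of dim transcripts. The deposited values are the authors' processed intensity on a linear scale for 45101 probe sets. From the values, the mean of each array without its top and bottom 2% was 500, and the lowest value was 1, held by 3621 values. The program that summarised the probes into probe sets and scaled the arrays is not given in the sources used here.

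From the deposited intensities, the 64 control probe sets were removed and each array was scaled to a common 75th percentile. Values under the lowest 5th percentile of any array (2.42, which applied to 3.48% of values) were raised to it, and log2 was taken. Values at this floor have no order among themselves. Probe sets were named from the platform annotation: 34945 had 1 gene symbol, 932 had several and were left unnamed, and 9160 had none. Of the named ones, 34741 matched a current mouse gene by Entrez identifier and 0 symbols needed an update. Where a gene had several probe sets, as 9010 genes did, the one with the highest mean over all arrays stood for the gene, which left 18193 genes. The number of arrays limits the precision of every value: the median standard error of a difference between groups was 0.515 on the log2 scale.

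Background was taken as 31.1, the 95th percentile of the signals of 27 bacterial control probe sets that have no target in mouse RNA. This limit was added after the data had been examined. Where the dimmer group of a comparison lay below it, the brighter group's mean divided by 31.1 is given as "at least N-fold". Medians of gene lists are accompanied by a median in which such members stand at that bound, and members below background in both groups at 0, wherever the 2 medians lie far apart. Between 69% and 77% of probe sets lay above this limit on each array.

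Groups were taken from the sample labels: wild-type (WT) bulge, WT hair germ, Runx1 iTG bulge and Runx1 iTG hair germ, with 2 arrays each. The labels call the samples biological replicates, so each p-value measures the spread among samples so labelled, with 2 per group. By their sex-linked signals, given below, the 2 arrays of each group differed in sex, so this spread includes sex. Whether bulge and hair germ samples of one replicate number share an animal is not given in the sources used here. Comparisons that use both populations may therefore not rest on independent samples. One linear model with a mean per group was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance (residual degrees of freedom 4, total 9.87 after moderation). There were 6 contrasts: Runx1 iTG minus WT in each population, hair germ minus bulge in each genotype, the interaction, and the genotype difference averaged over both populations. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p of a gene given in the text comes from this limma fit unless another setting is named.

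For gene groups, 30 lists with 569 genes were fixed, of which 531 were measured. They cover follicle compartments, signalling pathways, metabolism, stress and markers of other cell types. Each list was tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists. It was tested again with a correlation estimated from the data. The limma fry test was run beside it. Fry tests whether a list's genes move, on balance, one way, and its mixed form tests whether they change in either direction. For list members, the count after adjustment over the list alone is given beside the count over all genes. Genes to name were taken by a rule. Runx1 and the sort genes Cd34, Itga6 and Krt15 are always named. Then follow up to 10 genes per direction with the largest difference among those past the threshold whose groups did not overlap and whose brighter group reached the median of all probe sets (130), without clone-type symbols, Xist and Y-linked genes. Where fewer than 5 passed, the 5 with the smallest unadjusted p are named. Of each list discussed, up to 4 members are named by unadjusted p. The groups, contrasts, lists, naming rule and the alternatives below, except where said, were chosen before the data were examined.

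Comparisons that share arrays were set beside 100 simulated sets of unchanged groups, with the overlap of independent lists for counts. The fit was tested on simulated data, in 20 simulated sets for Runx1 iTG minus WT in bulge over 18193 genes with 200 genes changed. The changed genes were drawn outside the 40% dimmest genes, with independent noise at each gene's moderated spread. The fit recovered 14.8% of 2-fold, 78.6% of 4-fold, 94.3% of 8-fold and 99.5% of 16-fold changes, and 6.57% of calls were false. These shares may not hold for dim genes or for a contrast in which few genes change. Alternatives tried were the mean of a gene's probe sets, every probe set separately, leaving out the 40% dimmest genes, no intensity trend, quantile normalization and an offset of 32 before log2. Others were replicate number as a fixed or random block, only the groups compared, only the arrays of postnatal day 20, leaving out each array, an adjusted p under 0.1, an added 2-fold limit, and a 2-fold limit in every pair of arrays without a test. The deposited scaling and a block for replicate number over all 4 groups were added after seeing the data. Replicate 1 of every group had high Y-linked Eif2s3y signal (1850 to 2420) and low Xist (30.2 to 72.5), and replicate 2 the reverse (Eif2s3y 2.42 to 22.2, Xist 9970 to 11100), so sex followed replicate number equally in all 4 groups. No genome coordinates are given, since the annotation used here pairs probe sets with genes only.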

Results

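The series asked how raised levels of the transcription factor Runx1 change hair follicle stem cells at rest. Mice carried a Runx1 transgene (labelled Runx1 iTG) or were WT, and all were fed doxycycline at 1 g per kg of food for 1 day. The treatment record names repression of H2BGFP as the purpose of doxycycline. Whether the mice carried H2BGFP, and how doxycycline acts on the transgene, is not given in the sources used here. Skin was taken in telogen, the resting phase of the hair cycle, at postnatal day 20, except that replicate 2 of both transgenic populations was labelled day 21. Keratin 15-GFP and α6-integrin positive cells were sorted by the surface protein CD34. CD34-positive cells were collected as bulge, where long-lived stem cells reside. CD34-negative cells were collected as hair germ, the cluster below the bulge that starts a new hair. Each of the 4 groups had 2 arrays. Deposited median intensity lay between 101.7 and 162 on the 8 arrays. Across genes, which are not independent replicates, Spearman's rho was 0.949 to 0.958 between replicates, 0.943 to 0.959 between genotypes of one population and 0.888 to 0.92 between populations. The first principal component held 39.3% of the variance and separated bulge from hair germ.

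Runx1 was far brighter in the transgenic samples, as the label of the transgene names. The probe set that stood for the gene was the brightest over all 8 arrays, a mean to which the rise itself adds. It rose 21.2-fold in bulge, from a mean signal of 771.1 to 16330 (log2 difference 4.40, SE 0.25, n = 2 per group, adjusted p = 0.000147). In hair germ it rose 25.4-fold, from 492.1 to 12490 (4.67, SE 0.25, adjusted p = 8.46e-05). In WT samples it was not the brightest, as others stood at 2727 and 2203 in bulge and at 1556 and 1348 in hair germ. Of the other 5 probe sets that the annotation gives to Runx1 alone, 1 was higher by 2.17 in bulge (4.51-fold, adjusted p = 0.0842 over all probe sets) and rose by 2.35 in hair germ (5.11-fold, adjusted p = 0.042). The remaining 4 probe sets differed by −0.40 to 0.21 in bulge and lay lower in transgenic hair germ, at −2.77 to −1.43. None of these 4 passed over all probe sets (adjusted p between 0.298 and 0.71). When the mean of the 6 probe sets stood for the gene, the Runx1 difference was 0.99 in bulge (adjusted p = 0.689) and −0.29 in hair germ (adjusted p = 0.944). The call of the brightest probe set held whichever array was left out. It was lost without the intensity trend (adjusted p = 0.143 in bulge and 0.101 in hair germ) and with the day 20 arrays only (0.0745 and 0.078). With only the groups compared it was lost in bulge (0.0791) and kept in hair germ (0.0126).

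**Figure D1:**
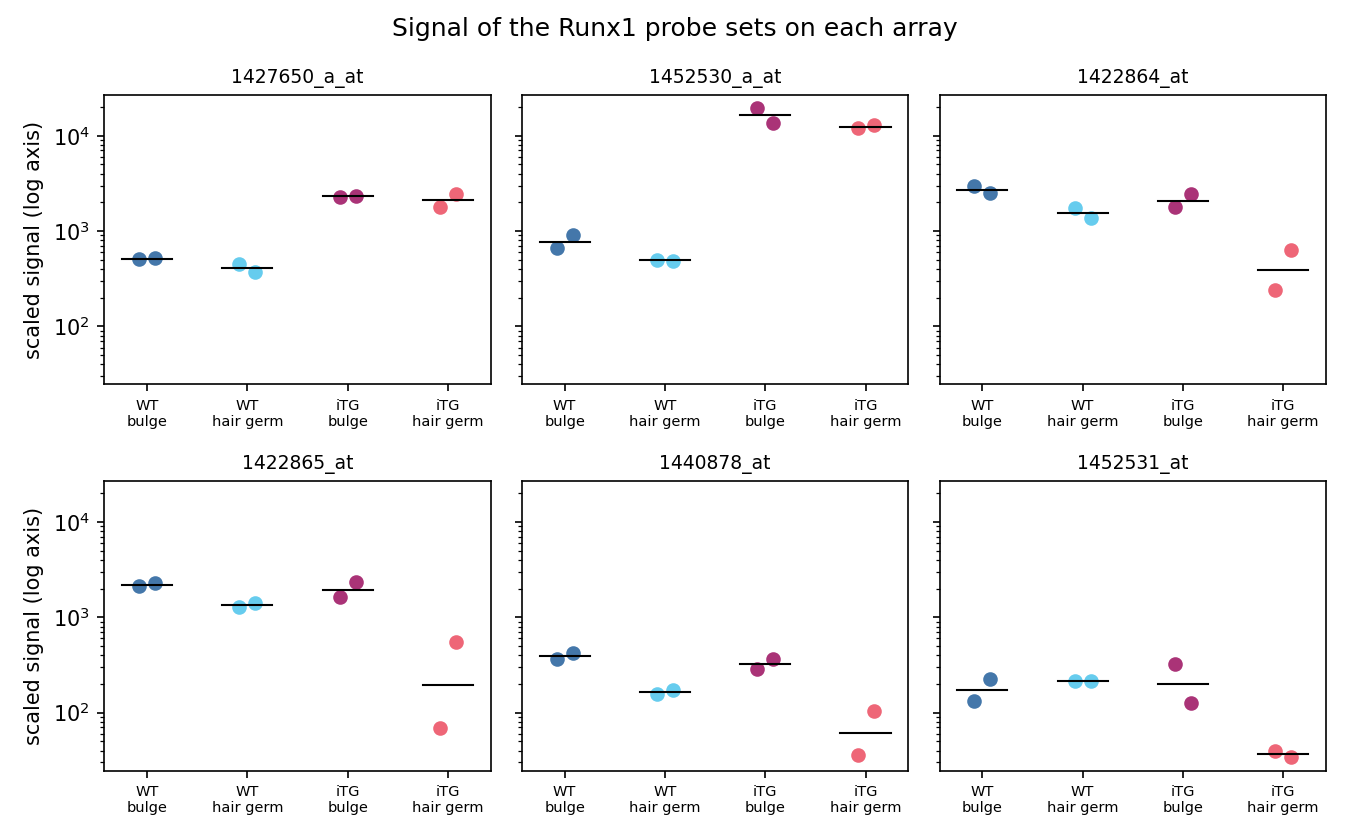
Scaled signal of the 6 Runx1 probe sets on each array (log axis), by group, with the geometric mean of each group as a black line (n = 2). In 2 of the probe sets both transgenic groups lie above WT, while in the other 4 the transgenic hair germ arrays lie below the other 6 arrays.

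The first comparison set transgenic against WT bulge cells, all of them after 1 day of doxycycline. Beside Runx1, 3 genes rose. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein GILZ, rose 8.5-fold (log2 3.09, SE 0.29, n = 2 per group, adjusted p = 0.0102). The carboxylesterase gene Ces1d rose 7.38-fold (2.88, SE 0.32, adjusted p = 0.0266), and the vasopressin receptor gene Avpr1a rose 4.15-fold (2.05, SE 0.25, adjusted p = 0.0418). In all, 4 genes were higher and 0 lower by limma, with 1084 genes at an unadjusted p under 0.05 against 909.6 given by chance. The genes nearest the threshold were Cyp2f2, a cytochrome P450 gene, at least 9.98-fold brighter in transgenic bulge (adjusted p = 0.0682), and Enc1 at −1.79 (adjusted p = 0.0821). Slc30a1 (−1.56), Fam107b (−1.66), Gdf10 (−3.51) and Ak4 (−1.39) lay lower with adjusted p between 0.236 and 0.374. The sort genes did not pass: Cd34 differed by −0.46, Itga6 by −0.02 and Krt15 by −0.25.

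Of the 30 lists, 3 were called higher in transgenic bulge by camera, and no list member other than Runx1 passed over all genes. Dissociation and immediate early genes, which respond within minutes to growth signals and to tissue handling, were higher for 18 of 22 members (median 0.29, adjusted p = 0.000259, but adjusted p = 0.242 with an estimated correlation). The 3 members that passed adjusted over the list alone were Fos at 1.85, Zfp36 at 1.26 and Dusp1 at 1.40. Upper follicle and sebaceous genes were called higher (21 measured, median 0.16, adjusted p = 0.0178, but adjusted p = 0.38 with an estimated correlation). Of its members, 4 passed adjusted over the list alone, among them the fatty acid desaturase gene Scd1 at 1.29 and the wax synthesis gene Far2 at 1.24. Cidea was at least 5.12-fold brighter. Basal interfollicular keratinocyte genes were called higher as well (11 measured, median 0.40, adjusted p = 0.0178, but adjusted p = 0.652 with an estimated correlation). The 3 members that passed adjusted over the list alone were Fos and the metallothionein genes Mt1 (1.07) and Mt2 (1.06). Bulge stem cell genes (median 0.06, adjusted p = 0.827), proliferation genes (median 0.00136, adjusted p = 0.827) and epidermal differentiation genes (median −0.14, adjusted p = 0.152) were not called. Tsc22d3 did not pass without WT bulge replicate 1 (adjusted p = 0.386), WT bulge replicate 2 (0.0983) or transgenic bulge replicate 1 (0.0537). Ces1d was lost in 6 of the 8 fits that left out an array and Avpr1a in all 8, with adjusted p up to 0.386. The number of genes was 1 without replicate 1 of WT or transgenic bulge, 2 without WT bulge replicate 2 or either transgenic hair germ array, and 11 without transgenic bulge replicate 2. With the mean of each gene's probe sets Tsc22d3 (log2 0.995, adjusted p = 0.74), Ces1d (2.39, 0.269) and Avpr1a (1.76, 0.599) did not pass, and without the intensity trend none did (0.224 to 0.305). With only the groups compared, or with the day 20 arrays only, 0 genes passed in bulge. With the offset Ces1d (0.12) and Avpr1a (0.111) were lost. The upper follicle and sebaceous call was lost without transgenic bulge replicate 2 (0.0609), with the day 20 arrays only (0.103) and with the offset (0.0719). The basal list's call was lost without WT bulge replicate 1 (median 0.21, 0.0647) or transgenic bulge replicate 1 (0.101).

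The same question was put to the hair germ. Here the chemokine gene Cxcl14 fell 6.73-fold (log2 −2.75, SE 0.22, n = 2 per group, adjusted p = 0.00229), from a mean signal of 3376 to 501.7, and Tle4, a Groucho-family co-repressor, fell 4.49-fold (−2.17, SE 0.25, adjusted p = 0.0395). Carboxypeptidase E (Cpe) rose 6.79-fold (2.76, SE 0.34, adjusted p = 0.0414), and Tsc22d3 rose 5.49-fold (2.46, SE 0.29, adjusted p = 0.0395). With Runx1, 3 genes were higher and 2 lower, and 1233 genes had an unadjusted p under 0.05. Close to the threshold lay the desmosomal cadherin gene Dsc2 (3.68, adjusted p = 0.0751) and Strip2 (at least 8.9-fold brighter, adjusted p = 0.0712). On the lower side these were Enc1 (−1.92, adjusted p = 0.0621), the upper follicle stem cell marker Lgr6 (−2.07, adjusted p = 0.0712) and Nucb2 (−2.51, adjusted p = 0.0751). Krt15 differed by −0.56 (adjusted p = 0.671) and Itga6 by −0.27 (adjusted p = 0.914), and Cd34 was below background in both groups.

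Camera called 8 lists in hair germ, and of all list members only Runx1 and Tle4, in the list of RUNX and CBFB genes, passed over all genes. Epidermal differentiation genes were lower for 23 of 27 members (median −0.61, adjusted p = 2.16e-06, but adjusted p = 0.597 with an estimated correlation). Examples are Ivl, a cornified envelope protein gene, at −1.16 and Notch3 at −1.39, and 0 members passed adjusted over the list alone. Integrin and basement membrane genes were lower (30 measured, median −0.55, adjusted p = 2.59e-06, but adjusted p = 0.597 with an estimated correlation). Adjusted over the list alone 2 passed, Egfl6 at least 5-fold and Itga2 at least 6.26-fold dimmer. Notch pathway genes were lower (14 measured, median −0.35, adjusted p = 0.00276, but adjusted p = 0.29 with an estimated correlation), and 5 members passed adjusted over the list alone, among them Lfng at −1.13 and the ligand gene Jag1 at −1.17. Immediate early genes were higher (22 measured, median 0.60, adjusted p = 2.16e-06, but adjusted p = 0.122 with an estimated correlation). Of these, 6 passed adjusted over the list alone, including Fos at 1.58, Ier2 at 1.45, Zfp36 at 0.93 and Egr1 at 0.91.

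Smaller shifts were called in 4 further lists of hair germ, each without a call at an estimated correlation. Bulge stem cell genes were lower (29 measured, median −0.17, adjusted p = 0.0291, but adjusted p = 0.756 with an estimated correlation). Adjusted over the list alone, 6 passed, including Nfatc1, a regulator of stem cell quiescence, at −1.21, Tcf7l2 at −0.97 and Postn at −1.38. BMP and TGF-beta pathway genes were lower (35 measured, median −0.19, adjusted p = 0.0419, but adjusted p = 0.756 with an estimated correlation). Ltbp1 at −2.23, Tgfbi at −1.81 and Id4 at −1.33 passed adjusted over the list alone. Lipid and cholesterol metabolism genes were higher for 18 of 21 members (median 0.29, adjusted p = 0.0198, but adjusted p = 0.756 with an estimated correlation). Scd2 at 3.05 and Abcg1 at 1.53 passed adjusted over the list alone. Glycolysis and hypoxia genes were higher (19 measured, median 0.31, adjusted p = 0.0198, but adjusted p = 0.667 with an estimated correlation). The member that passed adjusted over the list alone was adrenomedullin (Adm) at 2.75. Upper follicle and sebaceous genes (median 0.16 but mean −0.10, adjusted p = 0.661) and proliferation genes (median −0.08, adjusted p = 0.513) were not called. Neither in bulge nor in hair germ did camera call the lists of hair germ and early progenitor genes (adjusted p = 0.789 and 0.561), CDK inhibitors (0.458 and 0.572), WNT (0.247 and 0.265) or Hedgehog genes (0.947 and 0.819). RUNX and CBFB genes (0.53 and 0.866), apoptosis genes (0.53 and 0.572), p53 targets (0.827 and 0.684) and interferon response genes (0.789 and 0.513) were not called either. Markers of melanocytes (0.53 and 0.561), fibroblasts (0.551 and 0.693), immune cells (0.827 and 0.513) and endothelium (0.648 and 0.572) did not separate the genotypes.

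Among the hair germ calls, Cxcl14 was lost in 1 of the 8 fits that left out an array, without WT hair germ replicate 1 (adjusted p = 0.115). Tsc22d3 (up to 0.513), Cpe (up to 0.289) and Tle4 (up to 0.324) were lost in all 8. The number of genes was 1 without WT hair germ replicate 1, 2 without any 1 of the bulge arrays or transgenic hair germ replicate 1, and 8 without WT hair germ replicate 2. With only the day 20 arrays it was 0, with an adjusted p of 0.104 for Cxcl14. With only the groups compared it was 1, and Cxcl14 did not pass (0.411). With the mean of each gene's probe sets Tsc22d3 (1.30, 0.431), Cpe (1.77, 0.521) and Tle4 (0.0924) did not pass, with quantile normalization none of these 3 did (0.0522 to 0.067), and with the offset Cpe did not (0.0575). Without the intensity trend Cxcl14 was lost as well (0.165). Without WT hair germ replicate 1 the bulge (adjusted p = 0.578), BMP and TGF-beta (0.501), lipid (0.496) and Notch (0.063) lists were no longer called. The medians of the bulge list (0.0125) and the BMP and TGF-beta list (0.0644) then turned positive, and that of the lipid list was 0.0978. Without transgenic hair germ replicate 1 this held for the bulge, BMP and TGF-beta, lipid and glycolysis lists (0.459 each), with medians of −0.0993, −0.0365, 0.137 and 0.105. The glycolysis call was lost without WT hair germ replicate 2 too (0.216). The BMP and TGF-beta call was also lost without any 1 of the bulge arrays (0.0563 to 0.0624), with the mean of probe sets (0.124), without dim genes (0.0775) and with the offset (0.0567). The bulge list's call was lost with the mean of probe sets (0.0766) and without either transgenic bulge array (0.0563 and 0.0573).

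**Figure D2:**
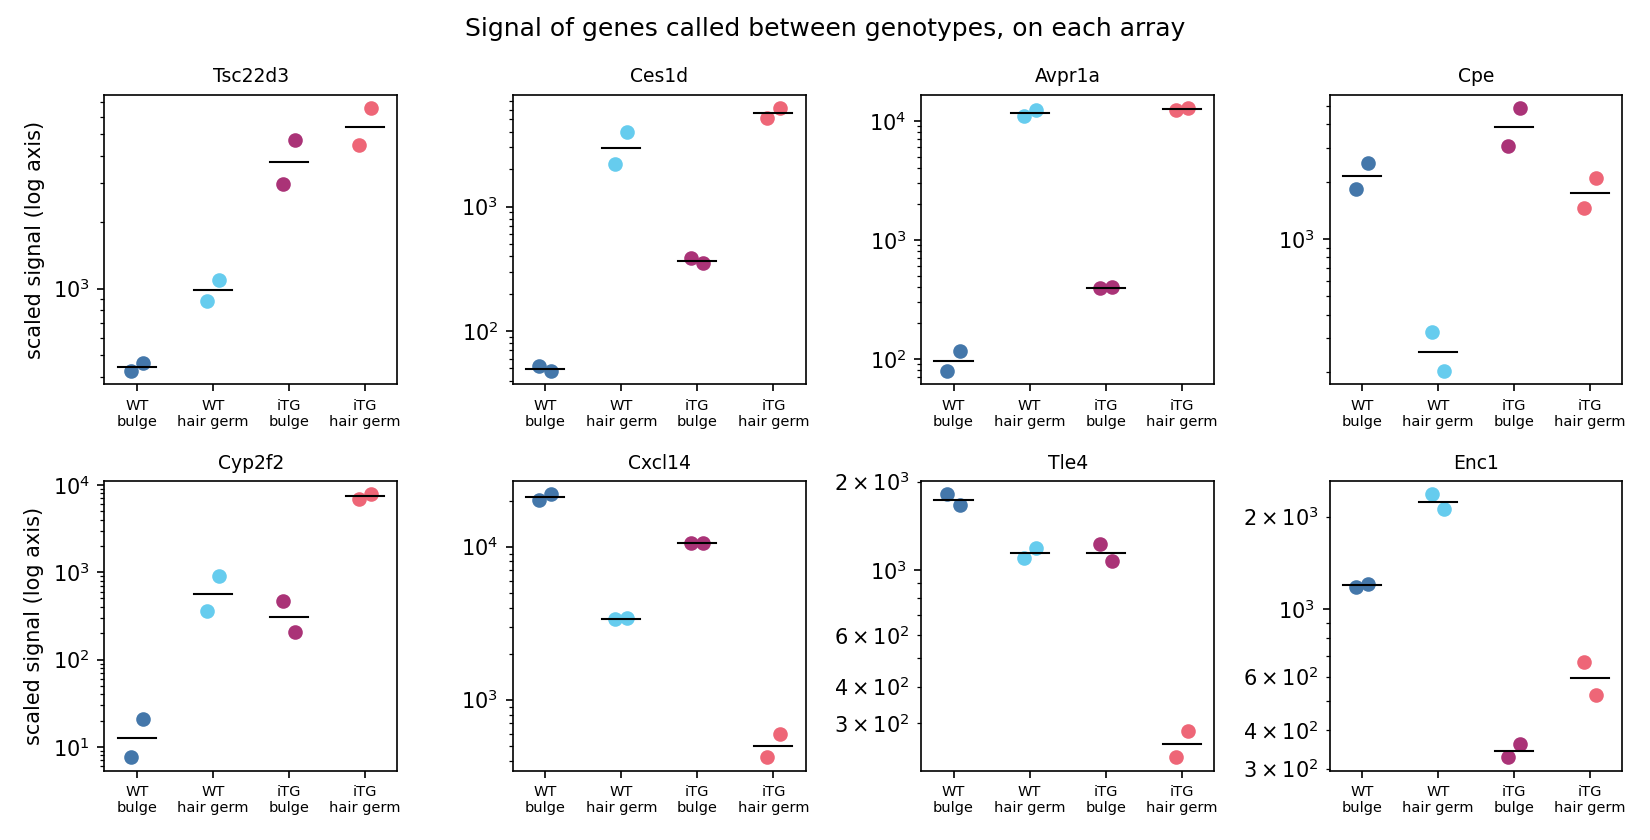
Scaled signal per array (log axis) of 8 genes called between genotypes in at least 1 comparison, with the geometric mean of each group as a black line (n = 2). Tsc22d3 is higher in all 4 transgenic arrays, Cxcl14 and Tle4 lie lowest in transgenic hair germ, and Avpr1a and Ces1d are brighter in hair germ than in bulge of either genotype.

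Averaged over both populations, 6 genes rose and 3 fell with the transgene, and 1456 genes had an unadjusted p under 0.05. Runx1 rose 23.2-fold (adjusted p = 3.89e-06), Cyp2f2 at least 11.4-fold (adjusted p = 0.0081; WT bulge lay below background) and Tsc22d3 6.83-fold (2.77, SE 0.21, adjusted p = 0.00112). The globin gene Cygb, also below background in WT bulge, rose at least 4.76-fold (adjusted p = 0.0254), Ces1d 3.76-fold (1.91, adjusted p = 0.0237) and Cpe 3.5-fold (1.81, adjusted p = 0.0448). Cxcl14 fell 3.67-fold (−1.87, SE 0.16, adjusted p = 0.00215), Enc1 3.62-fold (−1.86, SE 0.18, adjusted p = 0.00581) and Tle4 2.61-fold (adjusted p = 0.036). H60c (−2.18) and Vwa1 (−1.75), each with an adjusted p of 0.0588, did not pass. Runx1 and Tsc22d3 passed whichever array was left out. With the mean of each gene's probe sets Runx1 (0.35, 0.752), Tsc22d3 (1.15, 0.239), Ces1d (0.112), Enc1 (0.112) and Cpe (0.74, 0.686) did not pass, and without the intensity trend Runx1 alone passed. Cpe was also lost with quantile normalization (0.0634), and Cpe and Ces1d with the offset (0.0571 each). Cxcl14 was lost without WT bulge replicate 1 (0.0502) or WT hair germ replicate 1 (0.0515), Cyp2f2 and Enc1 in 5 of the 8 such fits, Ces1d and Cygb in 7 and Cpe and Tle4 in 8, with adjusted p up to 0.24. The count was 2 without replicate 1 of WT bulge or WT hair germ, 5 without WT bulge replicate 2, 3 without transgenic bulge replicate 1 or transgenic hair germ replicate 2, 4 without transgenic hair germ replicate 1, and 1 with the day 20 arrays only.

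In this average, camera called 5 lists, none of them with an estimated correlation and none with a member past the threshold over all genes. Immediate early genes were higher for 18 of 22 members (median 0.53, adjusted p = 3.76e-08, but adjusted p = 0.0782 with an estimated correlation). Adjusted over the list alone, 9 members passed, led by Fos at 1.71 and Zfp36 at 1.09. Epidermal differentiation genes were lower (median −0.43, adjusted p = 9.59e-06, but adjusted p = 0.507 with an estimated correlation). Integrin and basement membrane genes were lower too (median −0.31, adjusted p = 2.14e-05, but adjusted p = 0.507 with an estimated correlation), and 4 of them passed adjusted over the list alone, for example Itga3 at −0.93. Notch pathway genes were lower (median −0.34, adjusted p = 0.0139, but adjusted p = 0.461 with an estimated correlation). Adjusted over the list alone 6 were lower and 1 higher, among them Jag1 at −0.88 and Lfng at −0.73. Glycolysis and hypoxia genes were called higher (median 0.19, adjusted p = 0.0139, but adjusted p = 0.507 with an estimated correlation). Adm at 2.91 and Ddit4 at 0.91 passed adjusted over the list alone. The Notch call was lost without WT hair germ replicate 1 (0.085), transgenic bulge replicate 2 (0.101) or with the day 20 arrays only (0.0628). The glycolysis call was lost with quantile normalization (0.0771) and without WT hair germ replicate 2 (0.0799), transgenic bulge replicate 1 (median 0.0341, 0.232) or transgenic hair germ replicate 1 (median 0.0892, 0.179).

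The populations were then compared within each genotype. In WT mice, 571 genes were higher and 690 lower in hair germ than in bulge, and 3830 genes had an unadjusted p under 0.05. Among the genes with the largest differences, several handle lipids. Pparg, the regulator of adipocyte and sebocyte differentiation, was at least 47.8-fold higher (n = 2 per group, adjusted p = 0.000109). Lipoprotein lipase (Lpl) was at least 142-fold higher, the lipid droplet gene Cidea at least 48.3-fold, Acaa1b 91.1-fold (log2 6.51, SE 0.59) and Ces1d 59.1-fold. Avpr1a rose 122-fold, from 95.42 to 11620 (6.93, SE 0.25, adjusted p = 1.78e-06). Tlcd3b (at least 49.3-fold), Kank4 (at least 14.7-fold), the potassium channel gene Kcnk1 (at least 31-fold) and Chil1 (at least 24.4-fold) followed. Cd34, the gene of the sort marker, was at least 286-fold lower in hair germ. Other genes lower in hair germ were Col6a1 (102-fold, SE 0.89), Col6a2 (at least 70.7-fold), Chat (at least 47.4-fold), Pi15 (at least 44.3-fold), Has2 (at least 35.6-fold), Pdzrn4 (at least 35.1-fold), Kcnk2 (at least 27-fold), Plcl1 (at least 22.3-fold) and Atp2a3 (at least 18.5-fold). Krt15 differed by −0.74 (adjusted p = 0.0874), Itga6 by 0.07 (adjusted p = 0.9) and the brightest Runx1 probe set by −0.65 (adjusted p = 0.163).

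Camera called 14 lists in WT. Of 29 bulge stem cell genes, 24 fell and 5 did not pass (27 fell adjusted over the list alone; median −2.46, adjusted p = 5.38e-29, but adjusted p = 0.0932 with an estimated correlation). Lhx2 fell by 4.22, Tnc by 5.86, Tgm5 by 4.71 and the BMP antagonist gene Grem1 by 6.17. Of 21 upper follicle and sebaceous genes, 16 rose and 5 did not pass (16 rose and 1 fell adjusted over the list alone; median 3.02, adjusted p = 3.48e-19). This list was also called with an estimated correlation (adjusted p = 0.016). Far2 rose by 4.68, Elovl6 by 3.35 and Acsbg1 by 3.88. Of 29 proliferation genes, 10 rose and 0 fell (27 rose adjusted over the list alone; median 1.73, adjusted p = 4.01e-16, but adjusted p = 0.24 with an estimated correlation). The replication genes Mcm6 and Mcm3 rose by 1.87 and 1.81, and the mitotic genes Aurka and Ccnb2 by 1.93 and 2.18. Lipid and cholesterol metabolism genes were higher, with 5 of 21 risen (9 risen and 3 fallen adjusted over the list alone; adjusted p = 1.35e-05, but adjusted p = 0.24 with an estimated correlation). Scd1 rose by 2.79 and Srebf1 by 2.24.

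Hair germ and early progenitor genes were called lower in WT hair germ, with 10 fallen and 2 risen of 28 (13 fallen and 6 risen adjusted over the list alone; adjusted p = 0.0171, but adjusted p = 0.394 with an estimated correlation). The members that fell included the WNT receptor partner gene Lgr5 at −4.73 and the transcription factor genes Trps1 at −3.25, Msx2 at −3.88 and Dlx3 at −3.79. The median of this list was −0.87 and shrank to −0.10 with dim members at their bound, and its call was lost without WT bulge replicate 1 (median 0.00662, adjusted p = 0.127). Integrin and basement membrane genes were lower (15 fallen, 1 risen of 30; 19 fallen and 2 risen adjusted over the list alone; adjusted p = 1.86e-09, but adjusted p = 0.24 with an estimated correlation). Egfl6 fell by 4.22 and Col7a1 by 2.81. Epidermal differentiation genes (6 fallen of 27, 14 fallen and 1 risen adjusted over the list alone; adjusted p = 1.35e-05, but adjusted p = 0.24 with an estimated correlation) included Calml3 at −3.53 and Lor at −1.72. Inner bulge, companion layer and wound keratins (2 fallen and 1 risen of 9; 4 fallen and 1 risen adjusted over the list alone; adjusted p = 0.00301, but adjusted p = 0.201 with an estimated correlation) included Krt6a at −6.02, and Krt75 was at least 17.5-fold lower.

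Of the signalling lists, camera called the Hedgehog, BMP and TGF-beta and WNT lists lower in WT hair germ, but not with an estimated correlation (adjusted p = 0.199 with an estimated correlation for the first and 0.24 for the others). Notch genes (median 0.00343, adjusted p = 0.677) and JAK-STAT and SOCS genes (median 0.14, adjusted p = 0.155) were not called. Hedgehog pathway genes had 5 fallen of 11 (7 adjusted over the list alone; adjusted p = 1.35e-05, but adjusted p = 0.199 with an estimated correlation; median −1.84). Gas1 fell by 2.47, Ptch1 by 1.84 and Gli1 by 3.54. BMP and TGF-beta pathway genes had 12 fallen and 3 risen of 35 (18 fallen and 3 risen adjusted over the list alone; adjusted p = 1.42e-05, but adjusted p = 0.24 with an estimated correlation; median −1.20). Gdf10 fell by 5.68 and Ltbp2 by 3.77, and the receptor gene Tgfbr2 rose by 2.45. WNT pathway genes had 9 fallen and 1 risen of 37 (13 fallen and 3 risen adjusted over the list alone; adjusted p = 0.00559, but adjusted p = 0.24 with an estimated correlation). Their median was −0.19, and −0.06 with dim members at their bound. The antagonist genes Sfrp1 and Dkk3 lay at −5.11 and −4.92, and the receptor gene Fzd2 at −3.78. Catagen growth factor genes had 2 fallen of 14 (3 adjusted over the list alone; adjusted p = 0.0171, but adjusted p = 0.24 with an estimated correlation), among them Bdnf at −2.23. Immediate early genes had 3 risen of 22 (5 adjusted over the list alone; adjusted p = 0.0274, but adjusted p = 0.24 with an estimated correlation). These were Egr2 at 3.15, Fos at 1.74 and Egr1 at 1.31. The immediate early call was lost without the dim genes (0.169), with quantile normalization (0.159) and without WT bulge replicate 2 (0.0503) or WT hair germ replicate 1 (0.0964). The catagen call was lost without WT hair germ replicate 2 (0.0561).

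Markers of other skin cells moved with the bulge fraction in part. Dermal fibroblast and papilla markers were lower in WT hair germ, with 5 fallen of 17 (5 adjusted over the list alone; adjusted p = 0.00135, but adjusted p = 0.24 with an estimated correlation). The collagen genes Col1a1 and Col1a2 lay at −5.07 and −4.06, and Fbln1 at −3.09. The median of this list was −0.59, and −0.19 with dim members at their bound. Melanocyte (adjusted p = 0.139), immune (0.274), endothelial (0.0508) and muscle, fat, nerve and red cell markers (0.46) were not called. The number of genes between the WT populations was 580 and 332 without WT bulge replicate 1 or 2, and 645 and 433 without WT hair germ replicate 1 or 2. Of 68 named genes that passed, 47 did so whichever array was left out, and none changed sign. Among the genes with the largest differences, Has2 (adjusted p = 0.16), Pi15 (0.0805), Pdzrn4 (0.119), Kcnk2 (0.0658) and Col6a1 (0.0548) did not pass without WT bulge replicate 2. Mcm6 (0.0783), Mcm3 (0.131), Aurka (0.12), Ccnb2 (0.167), Fos (0.159), Egr1 (0.143), Bdnf (0.19), Lor (0.129), Gli1 (0.0823) and Dlx3 (0.0565) were also lost without WT bulge replicate 2, and Ptch1 without WT bulge replicate 1 (0.0623). With the mean of probe sets Mcm6 (0.43, 0.638), Aurka (0.113) and Ptch1 (0.0718) did not pass.

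In transgenic mice, 818 genes were higher and 957 lower in hair germ than in bulge (4188 at an unadjusted p under 0.05). Pparg rose 132-fold (log2 7.04, SE 0.59, n = 2 per group, adjusted p = 0.000183) and the cell adhesion gene Clmp 66.7-fold (6.06, SE 1.05). On the transgenic bulge arrays Pparg stood at 30.47 and 32.06, at the background limit of 31.1. Its fold is therefore no more exact than the bound given in WT. Kcnk1 (at least 90.5-fold), the metabolic kinase gene Pdk4 (at least 64.7-fold) and the ectodysplasin receptor gene Edar (at least 44-fold, in 1 of its 2 probe sets) rose too, as did Mogat1 (at least 32-fold), Gsg1l (at least 20.7-fold), Cyp17a1 (at least 15.7-fold), Lcn2 (at least 11.5-fold) and Rassf6 (at least 6.92-fold). Krt6a fell 84.3-fold (−6.40, SE 0.30, adjusted p = 1.77e-05) and S100a4 74.6-fold (−6.22, SE 0.39). Cd34 (at least 209-fold), Col6a1 (at least 114-fold), Col6a2 (at least 76.6-fold), Egfl6 (at least 69.5-fold), Chat (at least 45.1-fold), Kcnma1 (at least 38.4-fold), Pdzrn4 (at least 32.1-fold) and Me3 (at least 8.76-fold) were lower. Krt15 fell by 1.05 (adjusted p = 0.017), while Itga6 (−0.18) and the brightest Runx1 probe set (−0.39) did not pass. The 4 Runx1 probe sets that were dimmer in transgenic hair germ fell against transgenic bulge, by 2.41, 3.31, 2.39 and 2.47 on the log2 scale (adjusted p between 0.00682 and 0.0317 over all probe sets).

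The 14 lists called in transgenic mice had the names of those called in WT, and each had its WT direction. Bulge stem cell genes fell in 28 of 29 (29 adjusted over the list alone; median −3.07, adjusted p = 7.42e-32, but adjusted p = 0.0785 with an estimated correlation), with Postn at −5.60. Upper follicle and sebaceous genes rose in 14 and fell in 1 of 21 (17 risen and 2 fallen adjusted over the list alone; median 2.27, adjusted p = 4.05e-13), and passed with an estimated correlation (adjusted p = 0.0338). Proliferation genes rose in 10 of 29 (23 adjusted over the list alone; median 1.54, adjusted p = 4.73e-12, but adjusted p = 0.243 with an estimated correlation), led by Mcm6 at 2.40. Lipid and cholesterol metabolism genes rose in 12 and fell in 2 of 21 (15 and 2 adjusted over the list alone; adjusted p = 1.26e-09, but adjusted p = 0.148 with an estimated correlation). Srebf1 rose by 2.90 and Fasn by 1.92. Integrin and basement membrane genes fell in 19 and rose in 2 of 30 (22 and 2 adjusted over the list alone; adjusted p = 8.91e-12, but adjusted p = 0.148 with an estimated correlation). Epidermal differentiation genes fell in 12 of 27 (17 adjusted over the list alone; adjusted p = 2.18e-08, but adjusted p = 0.177 with an estimated correlation).

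BMP and TGF-beta pathway genes fell in 15 and rose in 3 of 35 in transgenic mice (20 and 3 adjusted over the list alone; adjusted p = 1.88e-07, but adjusted p = 0.177 with an estimated correlation), with Id4 at −3.33. Hedgehog genes fell in 5 of 11 (7 adjusted over the list alone; adjusted p = 0.000127, but adjusted p = 0.148 with an estimated correlation). Fibroblast markers fell in 7 of 17 (8 adjusted over the list alone; adjusted p = 0.000127, but adjusted p = 0.177 with an estimated correlation). Their median of −1.37 shrank to −0.11 with dim members at their bound. Hair germ and early progenitor genes fell in 9 and rose in 4 of 28 (10 and 4 adjusted over the list alone; adjusted p = 0.0089, but adjusted p = 0.348 with an estimated correlation). WNT pathway genes fell in 10 and rose in 1 of 37 (12 and 1 adjusted over the list alone; adjusted p = 0.00285, but adjusted p = 0.232 with an estimated correlation; median −0.32, and −0.23 with dim members at their bound). Inner bulge, companion layer and wound keratins fell in 5 and rose in 1 of 9 (5 and 1 adjusted over the list alone; adjusted p = 0.000946, but adjusted p = 0.148 with an estimated correlation). Catagen growth factor genes fell in 4 of 14 (4 adjusted over the list alone; adjusted p = 0.0205, but adjusted p = 0.241 with an estimated correlation). Immediate early genes rose in 5 of 22 (6 adjusted over the list alone; adjusted p = 0.0071, but adjusted p = 0.148 with an estimated correlation). Without transgenic bulge replicate 1 the hair germ and immediate early lists were not called (0.0846 each). The catagen list was lost without transgenic bulge replicate 2 (0.0658) and with the day 20 arrays only (0.0844). The number of genes was 1073 and 747 without transgenic bulge replicate 1 or 2, 637 without transgenic hair germ replicate 1 and 361 with the day 20 arrays only. Of 73 named genes that passed, 54 did so whichever array was left out, and none changed sign. Krt15 was lost without transgenic bulge replicate 1 (0.0819) or 2 (0.0716) or hair germ replicate 1 (0.149), Clmp without transgenic hair germ replicate 1 (0.0512) and Pdzrn4 without transgenic bulge replicate 2 (0.0674). With the mean of its probe sets Edar did not pass (0.126).

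**Figure D3:**
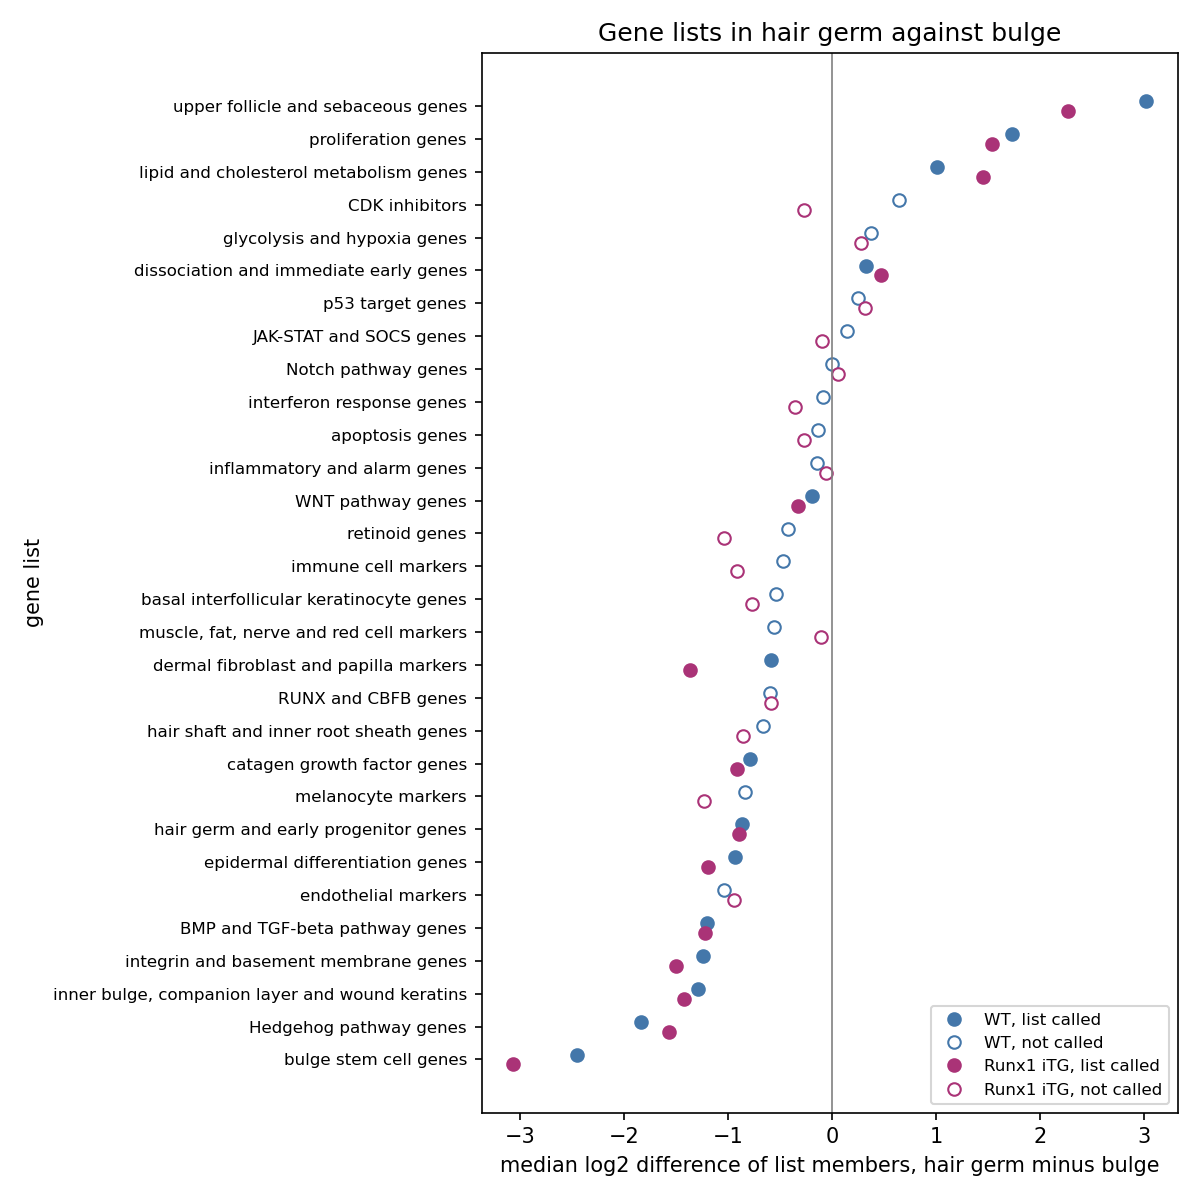
Median log2 difference, hair germ minus bulge, of the measured members of each of the 30 gene lists in WT and Runx1 iTG mice, with filled circles for lists called by camera at the preset correlation. Upper follicle and sebaceous genes lie highest (3.02 and 2.27) and bulge stem cell genes lowest (−2.46 and −3.07).

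Genes called between the populations overlapped between the genotypes: 412 were higher in hair germ in both, against 25.7 for independent lists. Another 511 were lower in both, against 36.3, and 0 went opposite ways. Across genes, which are not independent replicates, the slope of the transgenic on the WT difference was 0.62 and r was 0.59. Among the brighter 60% of genes the slope was 0.90 and r was 0.84. The reverse slopes, of the WT on the transgenic difference, were 0.565 and 0.78. Noise in the variable regressed on lowers a slope, and both directions lay under 1. A slope under 1 is therefore not evidence of a smaller population difference in transgenic mice. The interaction, which asks whether the transgene acted differently in the populations, called 0 genes by limma, with 839 at an unadjusted p under 0.05, against 909.6 given by chance, and a smallest adjusted p of 0.91. The genes with the smallest unadjusted p, none of which passed, were Rassf6 (at least 2.33, with transgenic bulge below background), Plau (2.79), Dsc2 (3.88), Nrp1 (4.03) and Ncoa4 (1.56) on the higher side. On the lower side they were Cxcl14 (−1.75), Avpr1a (−1.94) and Ascl2 (−3.11). Dusp26 (−3.84) and Alox12b (−3.05) were there too, by at least that size, as WT bulge and transgenic hair germ lay below background. The calls of Avpr1a and Ces1d in bulge, and of Cxcl14, Tle4 and Cpe in hair germ, are therefore not shown to differ between the populations.

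The last comparison asked whether transgenic bulge cells had moved toward the WT hair germ profile. Of the 4 genes that rose in transgenic bulge, Avpr1a, Ces1d and Tsc22d3 were among the 571 genes higher in WT hair germ. Both calls rest on the same WT bulge arrays. Avpr1a stood at 95.42 in WT bulge, 396.1 in transgenic bulge and 11620 in WT hair germ, and Ces1d at 49.81, 367.6 and 2942. The rise in transgenic bulge was 2.41% of the transgenic hair germ level above WT bulge for Avpr1a and 5.7% for Ces1d. Over all genes, the transgene's difference in bulge and the WT population difference had r = 0.34 and rho = 0.33. Both subtract the same WT bulge arrays, and unchanged groups gave r = 0.499. The covariance was 0.316 against 0.301 (SD 0.00915) in simulated unchanged groups, a difference of 0.0156. With 1 WT bulge array on each side, the covariance was −0.0246 or 0.0605 depending on the split. The overlap of called genes decides nothing there, since Avpr1a, Ces1d and Tsc22d3 were not called in bulge with 1 WT bulge array. Leaving out transgenic bulge replicate 1 or 2 moved the covariance excess over the residual variance, 0.0148 with all arrays, to −0.0631 or 0.102. In hair germ, the transgene's difference and the WT population difference had a covariance of −0.2 against −0.301 in simulated groups. With 1 WT hair germ array on each side it was 0.179 or 0.0013 depending on the split. The transgene's differences in bulge and in hair germ, which share no arrays, had r = 0.10 across genes and a covariance of 0.0645 against −2e-05 in simulated groups. The simulated noise was independent between genes, so its spread is too narrow to judge any of these covariances. Leaving out 1 transgenic bulge array moved the bulge excess by far more than that spread. Arrays of one replicate number may also share an animal. The covariance of 0.0645 therefore does not show that the transgene acted alike in both populations.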

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

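The second sebaceous list and the splits of the arrays were tested as written before their results were seen. All other tests in this part were chosen after the result was seen.

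Upper follicle and sebaceous genes differed between the populations in their response to the transgene: by camera on the interaction, their change in hair germ was lower than their change in bulge (21 measured, median −0.45, adjusted p = 0.00665, but adjusted p = 0.466 with an estimated correlation). The median of this list was 0.164 in bulge and 0.162 in hair germ, so the medians themselves did not differ. Lgr6 at −1.67 passed adjusted over the list alone. The second sebaceous list went the other way in the interaction (median 0.202, camera p = 0.0435, p = 0.234 with an estimated correlation). It was higher in transgenic hair germ (0.457, camera p = 0.00181, p = 0.0965 with an estimated correlation) and not in bulge (0.321, camera p = 0.451). Lipid and cholesterol metabolism genes differed the other way (21 measured, median 0.39, adjusted p = 0.00704, but adjusted p = 0.82 with an estimated correlation), with Scd2 at 3.60 and Abcg1 at 2.19 and 0 members past the threshold adjusted over the list alone. No member of either list passed over all genes. The upper follicle call was lost with the offset (0.0501) and without transgenic hair germ replicate 1 (0.0803). The lipid call was lost without WT hair germ replicate 1 (0.235), transgenic bulge replicate 2 (median 0.18, 0.131) or transgenic hair germ replicate 1 (0.145).

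Probe sets without a single assigned gene, 10092 in number, were in no comparison by gene. With every probe set fitted separately, 222 of them passed between hair germ and bulge in WT (88 higher, 134 lower) and 341 in transgenic mice (116 higher, 225 lower). In the genotype difference averaged over both populations 5 passed (3 higher, 2 lower). In either genotype difference alone and in the interaction 0 passed by limma, with 511 in bulge, 551 in hair germ and 383 in the interaction at an unadjusted p under 0.05.

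The Runx1 probe sets moved apart in transgenic hair germ. CD34-positive bulge cells carried over into WT hair germ are argued against. Cd34 there stood at 0.159% of its bulge signal (0.597% on the higher array), where the drop of the 4 lower probe sets would need 56.1%. The fraction was sorted as CD34-negative, so this measure cannot exclude bulge cells without CD34. The 3' over 5' log2 ratio changed by −0.172 for Gapdh and −0.02 for Actb, so it showed no loss of 5' signal in transgenic hair germ. How far this ratio responds to RNA quality after such amplification was not tested, so RNA quality stays open. Transgenic hair germ replicate 1, with the lower mean of the 4 probe sets, had the lowest deposited median of all arrays (101.7). It also had the most values at 1 (709) and the fewest probe sets above background (69%). A candidate explanation is less transcript of the endogenous gene in hair germ, with the transgene seen by the brighter probe sets alone. The 4 lower probe sets averaged −2.19 in hair germ (array means 6.12 and 7.55 against 9.04 and 9.02) and −0.16 in bulge, and the 4 had unadjusted p of 0.000588 to 0.0225 in hair germ. They were picked because they lay lower, and the positions of the probes on the transcript were not used here, so this explanation cannot be told apart from others.

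Upper follicle and sebaceous genes were higher in the CD34-negative fraction. The hair germ list was called lower there in WT (median −0.872, adjusted p = 0.0171, but adjusted p = 0.394 with an estimated correlation). Its median was −0.0954 with dim members at their bound and 0.00662 without WT bulge replicate 1, where the call was lost (adjusted p = 0.127). Scaling of the arrays is argued against for the upper follicle and sebaceous genes, whose lowest median in WT with quantile normalization, the deposited scaling or the offset was 2.94. For the hair germ list the median was −0.512 with quantile normalization and −0.921 with the deposited scaling. With the offset, which shrinks differences of dim genes and does not rescale the arrays, it was −0.319. As the limit set for this test included the offset, scaling stays open for this list. A candidate explanation is sebaceous or upper follicle cells inside this fraction. A second list of sebaceous gland genes had a median of 1.03 in WT (12 of 14 positive, 4 passed over all genes and 9 adjusted over the list alone; camera p = 1.3e-06, p = 0.0284 with an estimated correlation) and 1.36 in transgenic mice. Expression of these genes by hair germ cells themselves stays open.

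Immediate early genes and Tsc22d3 were higher in transgenic cells. Collection of replicate 2 of both transgenic populations a day later stays open. The day 20 arrays alone hold only replicate 1 of each transgenic population, male by its sex-linked signals, against WT arrays of both sexes. This subset thus swaps the day difference for a difference in sex and a lone transgenic array. In it the median of the list was still positive, at 0.21 in bulge and 0.64 in hair germ. At the preset correlation the list was called in both (largest adjusted p = 0.0416). With an estimated correlation it was not (0.687 and 0.552), nor with all arrays (0.242 and 0.122). Tsc22d3 lay higher by 2.76 and 2.18 on these arrays but did not pass (0.162 and 0.211). Handling and dissociation stress cannot be told apart from an effect of the transgene: the 5 heat shock members had a median of 0.139 and the other 17 of 0.68, between what handling would need and what would exclude it. A glucocorticoid type response may contribute. A list of 17 glucocorticoid response genes without Tsc22d3 had a median of 0.57 (14 positive, camera p = 9.9e-05, but p = 0.137 with an estimated correlation).

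For the 9 genes of the averaged genotype difference, the arrays were also regrouped. In a model with the split and the population, genotype gave 4 genes, and 3 of the 35 splits into 4 and 4 gave at least as many. The others follow the structure of the samples, namely replicate number, which follows sex (5 genes), and population (3331 genes, fitted without a population term). Of the remaining 32 splits, 31 gave 0 genes and 1 gave 2. The limit set beforehand for excluding chance, a share of splits under 0.05, was not met. By this test chance stays open for these genes.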

How the results depend on the processing

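Deposited scaling and the block for sex over all groups were chosen after seeing the data; the other alternatives were not. A fit that leaves out 1 array, or uses the day 20 arrays only, assumes that the lone sample of a group varies like the others.

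For Runx1 iTG minus WT in bulge, 4 genes passed. The count was 0 with the mean of probe sets, no intensity trend, only the groups compared or the day 20 arrays only, 2 with the offset or all probe sets separately, 7 without dim genes, and 9 at an adjusted p under 0.1. In hair germ 5 passed. There it was 0 with no intensity trend or the day 20 arrays only, 1 with the mean of probe sets or only the groups compared, 2 with quantile normalization, and 12 without dim genes or at an adjusted p under 0.1. The average gave 9 genes, but 1 with no intensity trend or the day 20 arrays only, 4 with the mean of probe sets, 17 with all probe sets, 30 without dim genes, and 34 at an adjusted p under 0.1. A 2-fold difference in every pair of arrays without a test gave 613, 705 and 42. The same rule between replicates 1 and 2 within each population gave 640 in bulge and 525 in hair germ. The interaction stayed at 0 genes by limma except for 3 without WT hair germ replicate 2. It has no value for the 2-fold pair rule or for only the groups compared.

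Hair germ minus bulge in WT gave 1261 genes, but 411 with no intensity trend, 752 with only the groups compared, 720 with the day 20 arrays only, 2078 with all probe sets, 2006 at an adjusted p under 0.1 and 2041 by the 2-fold pair rule. In transgenic mice it gave 1775, but 708 with no intensity trend, 832 with only the groups compared, 361 with the day 20 arrays only and 3142 with all probe sets. Fewer arrays and a looser threshold change a count by construction. For the other changes the cause was not tested. Of the 1261 and 1775 genes, 1158 and 1627 were shared with quantile normalization. The median difference of all genes between WT populations was −0.0812, and −0.138 with the deposited scaling and 0.0241 with quantile normalization.

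Leaving out 1 array gave 1 to 11 genes in bulge, 1 to 8 in hair germ, 332 to 1181 between WT populations, 637 to 1532 between transgenic populations, 0 to 3 in the interaction and 2 to 11 in the average. Of the genotype calls, Runx1 in each contrast and Tsc22d3 in the average were kept throughout. In bulge and in the average the largest counts came without transgenic bulge replicate 2. The lowest came without replicate 1 of either bulge group in bulge, and without replicate 1 of either WT group in the average. No named gene that passed changed direction. With a replicate block the average gave 15 genes. The sex block is the same model for the genotype differences, so its 15 genes are no second check. With replicate number within genotype as a random block the average gave 8. Replicate deviations of the groups had r of −0.0271 to 0.0822 over 6 pairs, none above 0.1. Sex follows the number, and whether arrays with one number share an animal is not given in the sources used here.

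With the mean of its 6 probe sets, Runx1 reversed in hair germ, to −0.291. This follows from the construction, which averages probe sets that moved apart. The overlap of bulge calls with WT population calls, 3 genes, was 0 with the mean of probe sets or no intensity trend, where 0 genes were called in bulge. It was 1 with the offset, 5 with quantile normalization and 6 without dim genes. With 1 WT bulge array to each comparison it decides nothing, since none of the 3 genes was then called in bulge. The excess covariance ran from −0.0631 to 0.102 without 1 array, and the slope between genotypes, 0.618, from 0.488 to 0.679. The slope was 0.899 without dim genes and 0.827 with the offset.

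Lists called were 3 in bulge, 8 in hair germ, 14 and 14 between populations, 2 in the interaction and 5 in the average. With an estimated correlation these fell to 0, 0, 1 and 1, 0 and 0. Fry gave 0, 0, 13 and 18, 0 and 1 in one direction, and 5, 8, 26 and 27, 0 and 12 in its mixed form. Without dim genes there were 5 in bulge and 5 in the interaction. The interaction also had 4 with the mean of probe sets, 1 with the offset, 6 with the replicate block and 5 with the day 20 arrays only. Leaving out 1 array gave 3 to 5, 4 to 9, 13 to 15, 13 to 16, 0 to 8 and 4 to 6. The cause was not tested.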

Other observations

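The test in this part was chosen after the result was seen. Genes bright in hair germ lay higher in transgenic than in WT bulge. Of the 20 genes brightest in WT hair germ among those called at least 16-fold higher there than in WT bulge, 18 did so. Over all 20 the median rise was 2.52% of their transgenic hair germ level above WT bulge (lowest −10.6%, highest 13.9%). These genes were chosen for low WT bulge values, which the comparison reuses. The hypothesis was that a small share of cells of the hair germ fraction entered the transgenic bulge samples, although the CD34 gate should remove them. With the genes chosen on 1 WT bulge array and the rise taken from the other, the median was 1.92% (13 of 20 higher) or 2.91% (18 of 20), against 1.24% (15 of 20) or 0.142% (12 of 20) between the WT bulge arrays themselves. The difference between the WT arrays starts from the array on which the genes were chosen as low. That choice alone raises it, so it is no measure of no change. A carry-over of cells may contribute to the rise of Avpr1a and Ces1d in bulge, but these splits do not decide it. The second sebaceous list was not called in transgenic bulge (median 0.321, camera p = 0.451), and it was higher in transgenic hair germ (0.457, camera p = 0.00181, p = 0.0965 with an estimated correlation). A change in the bulge cells themselves would give such values too.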
